A study of Rattus norvegicus with 6 samples.

How the data were processed

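Total RNA from the livers of 6 male Sprague-Dawley rats was labelled with Cy3 and hybridised to one-colour Agilent rat expression arrays, 1 array per rat. The labels place 3 arrays in a vehicle group and 3 in a group given nitrilotriacetic acid trisodium monohydrate (NTA, a chelator that binds metal ions such as zinc, iron and calcium) at 1000 mg/kg/day. The treatment protocol speaks of 3 animals per treatment, so each array was taken as 1 animal. The labels disagree on 2 points: the vehicle is purified water in the sample characteristics and corn oil in the treatment protocol, and the sampling time is 28 days in the series design but 9 weeks in the treatment protocol. Which of these holds was not settled here. The series title speaks of 10 chemicals; the chemicals other than NTA were not analysed here.

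Scanned images were quantified with Agilent Feature Extraction 10.7, per the submitters' processing notes, and 10.7.1.1, per the file headers, which also name the array design 035170 and the genome build rn4. The deposited scanner files give each spot's processed signal (gProcessedSignal), a background-subtracted intensity on a linear scale, per the file headers, with the median spot and local background intensities and flags beside it. The authors' deposited series table holds a linear ratio, the processed signal divided by the same array's 75th percentile: 100.0% of its probes matched that quotient within 0.0001 plus 0.2%. Its column medians were 0.098, 0.0977 and 0.0987 for the vehicle arrays and 0.096, 0.1 and 0.0969 for the NTA arrays. Its scale, direction and lack of centring were therefore known, and because it comes from the same signal it is not an independent check.

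Of 62976 spots per array, those of 61657 non-control probes were used. Between 62.4% and 64.5% of these probes were well above background on each array, 1 probe was saturated on 1 array, and 1 to 14 probes per array carried a non-uniformity flag and were set to missing. Main values were log2(gProcessedSignal) minus the array's 75th percentile of it. A probe was kept if it was well above background on all 3 arrays of at least 1 group. Probes were named by matching their unversioned accession to a RefSeq gene table of the assembly GRCr8. The match gave 1 symbol for 27460 probes (15284 genes) and none for 34197, which are unnamed here and were kept under their probe IDs. Because the array design and that table use different builds, no coordinates are given. For a gene with several probes the brightest over all 6 arrays was used; 5543 genes had more than 1 probe past the filter. This left 30353 features, made up of 11251 named genes and 19102 unnamed probes.

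NTA was compared with vehicle in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of adjusted p under 0.05. The moderated test used 4 residual and 2.54 prior degrees of freedom. For gene lists, limma's camera was run with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. It was repeated with an estimated correlation, and fry was run as another test. Of 42 lists of liver pathways and cell types, written before the data were examined, 41 had at least 5 measured members. Of their 982 entries, 977 were found in the gene table and 906 had a probe. With 3 rats against 3, the smallest two-sided p of an exact permutation test is 0.1, so single values were not tested that way. The number of arrays limits the precision.

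The genes named in the text follow a rule also fixed before the data were examined. It takes up to 8 genes per direction with the largest change among those past the threshold, separated between groups and above background on all arrays, and apart from these up to 3 genes per direction whose change is only bounded. Where fewer than 5 genes passed in a direction, those with the smallest p filled the list up to 5, given as values. For each gene list it takes up to 4 members past the threshold, or else the 2 with the smallest p. A fixed set of 16 genes was to be named whatever their values. Of the genes this rule and the calls within lists select, 3 are not reported here, though they stay in the tests. Genes with a provisional symbol were counted but not named. Where all arrays of a group were not well above background, the fold is a lower bound: the brighter group's mean against the dimmer group's mean of the higher, on each array, of the probe's own signal and the lowest signal among probes well above background.

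In simulated arrays with the real means and the spreads as moderated by eBayes, there were 5 datasets of 30350 features for the comparison of NTA with vehicle. In them 58.2% of 100 features changed 2-fold and 95.2% of 100 features changed 4-fold were called, and 4.6% of the calls were false. The shares called hold for independent normal noise and for that many true changes, which ease the adjusted threshold. They may be lower in the real data, where 9 features passed. A list of independent genes moved by 0.3 on the log2 scale was called in 5 of 5 datasets, and 0 of 200 unmoved lists by limma's camera. In the real lists the estimated correlation ran from −0.16 for adipose tissue to 0.81 for the interferon response. The 0 of 200 therefore gives no rate of false calls for lists of correlated genes.

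Alternatives fixed in advance were quantile and median normalisation, normexp background correction with an offset of 50, the deposited ratios, no filter and a filter on all arrays, flagged spots kept, the mean of a gene's probes, every probe on its own, eBayes with trend and robust, array weights, slide as a random block, a replicate block, treat against a 1.2-fold change, camera with an estimated correlation, fry, and leaving out each array in turn. The scanner files used here hold no mean spot signal, so normexp was run on the median spot signal. That substitution, the fit on named genes only and the fit with scan day as a block were chosen after seeing the data. The arrays lay on 3 slides and were scanned on 2 days. Slide 1 held vehicle replicates 1 and 2, slide 2 vehicle replicate 3 and slide 3 all NTA arrays; vehicle replicate 3 alone was scanned on day 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.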

Results

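Gene expression was measured in the livers of 3 rats given nitrilotriacetic acid (NTA) and 3 rats given vehicle, and the comparison between them is the only one the labels give. Signal was similar across arrays by 2 measures: 62.4% to 64.5% of probes were well above background, and the 75th percentile of the processed signal lay between 464 and 558. Vehicle replicate 3 differed in its median local background, 40 against 54 to 61 on the other arrays. It also had more probes flagged for non-uniformity, 14 against 1 to 9, and was alone on its slide and scan day. Across probes, which are not independent replicates, the arrays correlated at r = 0.987 to 0.991. The first principal component held 25.7% of the variance, with the NTA arrays between 18.8 and 33.4 and the vehicle arrays between −39.3 and −1.06. The second held 23.8%. Vehicle replicate 1 correlated more closely with NTA replicate 1 (r = 0.991) than with vehicle replicates 2 and 3 (r = 0.990 and 0.988). NTA replicate 1 correlated best with NTA replicate 2 (r = 0.991). The NTA arrays also shared a slide that held no vehicle array. All values below are log2 signal relative to the array's 75th percentile, as mean ± SD with n = 3 rats per group.

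A small set of liver transcripts was higher with NTA, and Gstp1 had the smallest p among the named genes. Gstp1, the pi-class glutathione S-transferase that is scarce in normal rat hepatocytes and marks preneoplastic foci in rat liver, rose from 3.23 ± 0.24 with vehicle to 5.94 ± 0.15 with NTA, a 6.51-fold difference (log2 2.70, SE 0.16; limma, Benjamini-Hochberg adjusted p = 0.0064). Its other 2 probes gave log2 differences of 2.77 and 2.68. Tubb3, a beta-tubulin best known from neurons, rose 4.03-fold, from −2.93 ± 0.23 to −0.92 ± 0.21 (log2 2.01, SE 0.17; limma, Benjamini-Hochberg adjusted p = 0.035), and its second probe gave a log2 difference of 2.50. Cyp26a1, the cytochrome P450 that breaks down retinoic acid, rose 2.79-fold, from −2.47 ± 0.05 to −0.99 ± 0.04 (log2 1.48, SE 0.09; limma, Benjamini-Hochberg adjusted p = 0.010). Only 1 probe was matched to Cyp26a1, so no other probe could be compared. For each of these genes all 3 NTA rats lay above all 3 vehicle rats, which the naming rule required. With normexp background correction the log2 differences of Gstp1, Tubb3 and Cyp26a1 were 2.72, 1.17 and 0.91.

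The call for the olfactory receptor gene Or4m1 rests on its first probe, which was not well above background on any vehicle array. In the processed signal that probe rose at least 6.68-fold, with measured means of −7.31 ± 0.09 with vehicle and −2.49 ± 0.69 with NTA (limma, Benjamini-Hochberg adjusted p = 0.012). The second probe of Or4m1 was not well above background on any of the 6 arrays, so it does not bear out the rise. Cross-hybridisation of the first probe was not tested. With normexp background correction the log2 difference of the first probe was 1.02, less than that bound (adjusted p = 0.32, and between 0.0076 and 0.32 over the alternatives that left no array out). Or4m1 passed in 2 of the 6 leave-outs, with limma adjusted p between 0.013 and 0.12. The remaining 5 features past the threshold were probes with no gene name here, all higher with NTA. Among them A_44_P347283 rose 10.9-fold (log2 3.45, SE 0.12) and A_44_P417083 rose 5.92-fold (log2 2.57, SE 0.12).

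**Figure D1:**
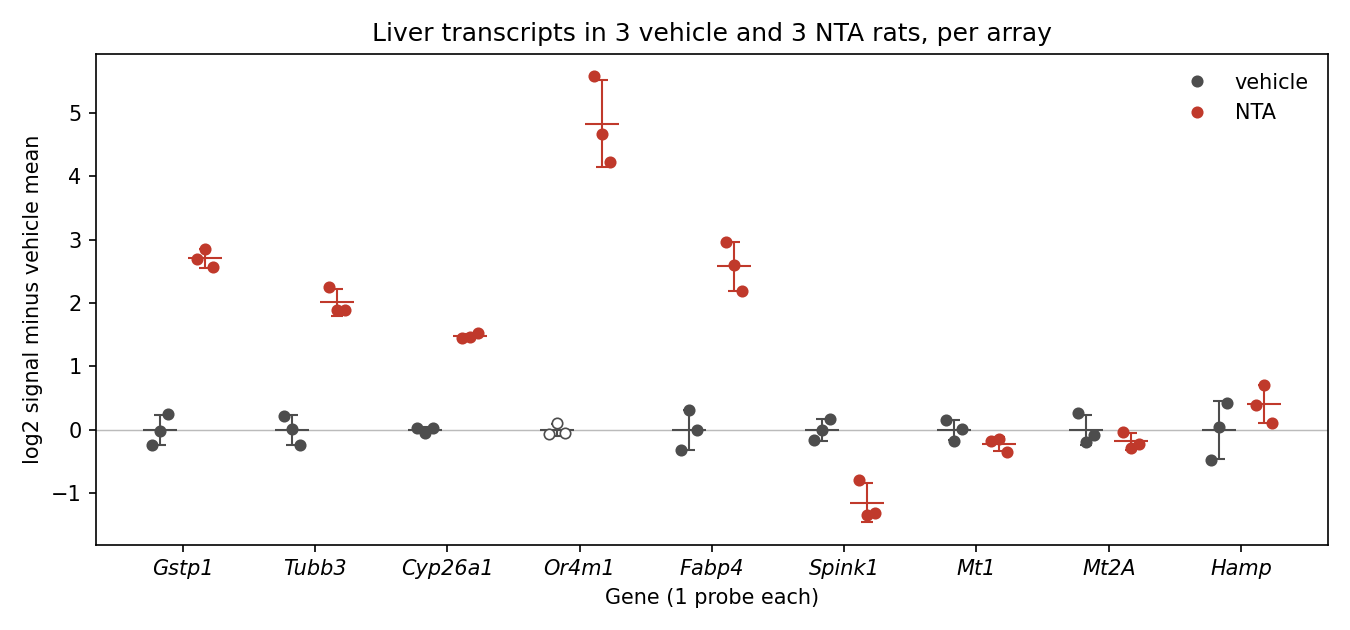
Log2 signal of 9 genes, each relative to its own vehicle mean (vertical axis, log2 units), for the 3 vehicle rats (grey) and 3 NTA rats (red); points are arrays, bars are mean ± SD, and open circles mark a group not well above background on any of its arrays. Gstp1, Tubb3, Cyp26a1 and Or4m1 passed the test; Fabp4, Spink1, Mt1, Mt2A and Hamp did not, and the size shown for Or4m1 is the measured one, of which only the bound of 6.68-fold is given.

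In total, limma called 9 of 30353 features at a Benjamini-Hochberg adjusted p under 0.05, 9 higher and 0 lower, all 9 at least 2-fold. At an unadjusted p under 0.05 there were 2298 features, 1110 higher and 1188 lower, which is 7.57% of those tested. The groups did not overlap for 13.6% of features, against 10% by chance for 3 against 3. In the fit with trend and robust, limma called 1 feature lower. Leaving out NTA replicate 2 left 1 call and leaving out NTA replicate 1 left 4. Without them the adjusted p of Gstp1 in limma was 0.056 and 0.076 (0.020 to 0.076 over the 6 leave-outs). Tubb3 and Cyp26a1 passed in none of the 6 leave-outs, with adjusted p between 0.10 and 0.18 and between 0.065 and 0.11. All NTA arrays shared 1 slide, so slide and treatment cannot be told apart. Slide as a random block gave 9 calls, and scan day as a block, or the 5 arrays of day 1 alone, gave 6, 5 of them among the 9.

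Fabp4, the fatty acid binding protein of adipocytes and macrophages, came next among named genes, at −4.59 ± 0.32 with vehicle and −2.01 ± 0.38 with NTA (log2 2.58, SE 0.24; limma, Benjamini-Hochberg adjusted p = 0.069, and 0.034 with trend and robust, in a range of 0.034 to 0.47 over the alternatives). With normexp background correction its log2 difference was 1.09. No named gene was lower past the threshold. The 5 separated genes with the smallest p in that direction had adjusted p between 0.369 and 0.377 in limma with Benjamini-Hochberg adjustment. Spink1, a secreted trypsin inhibitor, was at −0.31 ± 0.17 with vehicle and −1.46 ± 0.31 with NTA. The log2 differences of Mrpl18, a mitochondrial ribosomal protein, Copg2, a coatomer subunit, Armc9 and Zfp64 were −0.86, −0.64, −0.57 and −0.59. The other probe of Mrpl18 gave −0.14, another probe of Copg2 that was above background gave 0.13, and the other probes of Armc9 gave 0.03 and −0.15.

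Because NTA binds metals, the genes that answer to zinc, copper and iron were set out before the data were examined. None of them passed the test. The zinc-induced metallothioneins Mt1 and Mt2A had log2 differences of −0.22 (SE 0.13) and −0.18 (SE 0.15). The transferrin receptor Tfrc was at −0.07 (SE 0.20), the iron hormone hepcidin (Hamp) at 0.41 (SE 0.26) and heme oxygenase Hmox1 at 0.11 (SE 0.17), all with limma Benjamini-Hochberg adjusted p between 0.742 and 0.955. When 1 array was left out, Mt1 ran from −0.30 without vehicle replicate 2 to −0.14 without vehicle replicate 1, and Mt2A from −0.27 to −0.039 without the same arrays. Hamp ran from 0.17 without vehicle replicate 1 to 0.62 without vehicle replicate 3. The metallothionein and zinc list had a median of −0.11 over 13 measured genes (limma camera, Benjamini-Hochberg adjusted p = 0.52, and adjusted p = 0.82 with an estimated correlation). The copper list had a median of −0.10 over 11 genes (adjusted p = 0.59, and adjusted p = 0.85 with an estimated correlation). The iron list had a median of 0.03 over 22 genes (adjusted p = 0.41, and adjusted p = 0.80 with an estimated correlation). The zinc median ran from −0.15 without vehicle replicate 3 to −0.059 without NTA replicate 1, and the copper median from −0.12 without vehicle replicate 1 to −0.048 without vehicle replicate 3. In these 3 lists 0 genes passed in limma over all genes tested and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 0 and 1. In the zinc list the smallest p belonged to the importer Slc39a5 at 0.72 (SE 0.17) and the transporter Slc30a5 at −0.23 (SE 0.13). In the copper list they were the importer Slc31a1 at −0.40 (SE 0.17) and Commd1 at −0.19 (SE 0.11), and in the iron list the hepcidin inducer Bmp6 at 0.71 (SE 0.21) and hemojuvelin (Hjv) at −0.33 (SE 0.15). With 1 array left out, Slc31a1 ran from −0.55 to −0.24 and Hjv from −0.45 to −0.21. With normexp Bmp6 was at 0.20, Slc39a5 at 0.43 and Slc30a5 at −0.046.

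The other genes fixed in advance did not pass either, with limma Benjamini-Hochberg adjusted p between 0.657 and 0.985. Among the xenobiotic-inducible cytochromes P450, log2 differences were 0.05 (SE 0.14) for Cyp2b1, −0.50 (SE 0.31) for Cyp3a23-3a1 and −0.08 (SE 0.23) for Cyp4a1, and Cyp1a1 was not well above background in either group. When 1 array was left out, Cyp3a23-3a1 ran from −0.83 to −0.28. The p53 target Cdkn1a was at −0.08 (SE 0.14), while its other 2 probes gave −0.98 and −0.75. In lipid and glucose metabolism, Fasn, the fatty acid synthase, was at 0.07 (SE 0.43). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at −0.62 (SE 0.89) and the glucose-6-phosphatase G6pc1 at 0.07 (SE 0.45). The clock output gene Dbp was at −0.36 (SE 0.15). Mki67 was not analysed here, since no probe was matched to it.

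Of 41 gene lists, 10 shifted against all other genes by camera with its preset correlation of 0.01, 9 up and 1 down, and 13 had an unadjusted p under 0.05. Adjusted p values from camera and fry are Benjamini-Hochberg adjusted over the 41 lists throughout. With an estimated correlation 0 lists passed camera and 4 had an unadjusted p under 0.05, and 1 list passed fry. Every camera call below therefore holds only under the preset correlation. Of the 10 ways to split the 6 arrays into 3 and 3, the real one included, 5 gave 10 or more lists, with up to 15. A camera p as small as the real one came, with the real split counted, in 5 of the 10 for Kupffer cells and macrophages, in 3 for cholesterol synthesis and for oxidative phosphorylation, and in 2 for the cell cycle and for CAR and PXR targets. For the other 5 of the shifted lists the real split had the smallest.

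The defence genes under the transcription factor NRF2 shifted up, with a median log2 difference of 0.31 and 21 of 24 members above 0 (camera, Benjamini-Hochberg adjusted p = 1.4e-09, and adjusted p = 0.34 with an estimated correlation). In limma 1 member, Gstp1, passed over all genes tested and 5 passed adjusted over the list alone. Those 5 included, named after their values were seen, the aldo-keto reductases Akr1b8 and Akr7a3 and the conjugate exporter Abcc3, with log2 differences of 3.44 (SE 0.66), 1.60 (SE 0.27) and 1.36 (SE 0.38). Nqo1 and Gclm of the same list, also named after their values were seen, were at −0.19 (SE 0.56) and −0.25 (SE 0.35). The phase II conjugation list shifted up by a median of 0.15 over 27 genes (camera, adjusted p = 0.0011, and adjusted p = 0.34 with an estimated correlation), and Gstp1 was the 1 member past limma's threshold both over all genes tested and adjusted over the list alone. Without NTA replicate 1 this median was 0.069, and the call was kept. The list of CAR and PXR targets, the drug-inducible genes, had a median of 0.29 over 22 genes (camera, adjusted p = 0.0011, and adjusted p = 0.58 with an estimated correlation). In it 0 genes passed in limma over all genes tested and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05, Abcc3 and the glutathione transferase Gstm1 at 0.41 (SE 0.14). Both also belong to the NRF2 list and Gstm1 to the phase II list, so the shifts of these lists are not independent. Of the 22 CAR and PXR genes 17 lay above 0, while Cyp2b1 and Cyp3a23-3a1 were at 0.05 and −0.50. Without NTA replicate 1 the CAR and PXR median was 0.17 and its call was lost (adjusted p = 0.099), and without vehicle replicate 1 it was 0.19 and the call was kept.

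The cell cycle list shifted up by a median of 0.57, with 29 of 32 genes above 0 (camera, Benjamini-Hochberg adjusted p = 7.2e-14, and adjusted p = 0.38 with an estimated correlation). In limma 0 of its genes passed over all genes tested, 15 had an unadjusted p under 0.05, and 1 passed adjusted over the list alone, the mitotic kinesin Kif22 at 1.05 (SE 0.17). The replication licensing factor Mcm3 was at 0.62 (SE 0.15). Of the lists of blood and of non-hepatocyte liver cells, 4 also shifted up. The lists of stellate cells and fibroblasts, neutrophils, MHC class II and T and NK cells did not pass camera, with medians from −0.03 to 0.17. Sinusoidal endothelium markers had a median of 0.35 with 17 of 17 above 0 (camera, adjusted p = 1.4e-09, and adjusted p = 0.38 with an estimated correlation). Erythroid and blood genes had a median of 0.53 with 11 of 15 above 0 (adjusted p = 1.8e-05, and adjusted p = 0.36 with an estimated correlation). For B and plasma cell genes it was 0.67 with 8 of 8 above 0 (adjusted p = 4.9e-04, and adjusted p = 0.36 with an estimated correlation). For Kupffer cell and macrophage genes it was 0.38 with 21 of 22 above 0 (adjusted p = 2.6e-05, and adjusted p = 0.80 with an estimated correlation). With normexp background correction the median was 0.29 for the cell cycle and 0.21 for B and plasma cells, and with the mean of a gene's probes the latter was 0.45. Both calls were kept.

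In limma 0 genes of these 4 cell type lists passed over all genes tested; adjusted over the list alone there were 5, 3, 0 and 0. At an unadjusted p under 0.05, 10 endothelial genes were higher, 6 erythroid genes were higher and 1 lower, and 3 B cell and 2 Kupffer cell genes were higher. The 5 endothelial genes were the receptor kinase Tie1 at 0.63 (SE 0.14), the hyaluronan receptor Lyve1 at 0.54 (SE 0.12), Emcn at 0.78 (SE 0.18), Fcgr2b at 0.52 (SE 0.13) and Dnase1l3 at 0.62 (SE 0.16). The 3 erythroid genes were the blood group protein Rhd at 1.00 (SE 0.14), the erythroid heme synthesis enzyme Alas2 at 1.17 (SE 0.22) and carbonic anhydrase Car2 at 0.60 (SE 0.13). With normexp Lyve1 was at 0.32, Rhd at 0.59 and Abcc3 of the NRF2 list at 0.86. Emcn, Fcgr2b, Dnase1l3 and Car2 were named after their values were seen. The B cell receptor chain Cd79b and the B cell coactivator Pou2af1 were at 0.74 (SE 0.21) and 0.75 (SE 0.24), and the macrophage receptors Trem2 and Marco at 0.98 (SE 0.27) and 1.27 (SE 0.48). Cd79b was at 0.44 and Trem2 at 0.21 with normexp, Marco at 0.81 without vehicle replicate 3, and Pou2af1 at 0.36 with normexp and 0.23 with the mean of its probes. The Kupffer cell call was lost without vehicle replicate 3, or with scan day as a block, at a median of 0.08 (adjusted p = 0.15), and without NTA replicate 3 at 0.10 (adjusted p = 0.084). Without vehicle replicate 1 or NTA replicate 2 the median was 0.58 or 0.59. Biliary epithelium markers, in contrast, had a median of 0.07 over 15 genes (camera, adjusted p = 0.46, and adjusted p = 0.80 with an estimated correlation).

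Cholesterol synthesis genes shifted up by a median of 0.27, with 23 of 25 above 0 (camera, Benjamini-Hochberg adjusted p = 2.4e-06, and adjusted p = 0.68 with an estimated correlation). In limma 0 passed over all genes tested and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. The 2 with the smallest p were Hsd17b7 at 0.48 (SE 0.15) and Dhcr7, which catalyses a final step of the pathway, at 0.67 (SE 0.23). The cholesterol median was 0.14 without NTA replicate 2 and 0.17 without vehicle replicate 1 or with normexp, each with the call kept. On the arrays, the list's median for vehicle replicate 2, 0.23, lay above those of NTA replicates 1 and 3, 0.15 and 0.12. Oxidative phosphorylation was the 1 list that shifted down, by a median of −0.11 with 40 of 43 genes below 0 (camera, adjusted p = 4.9e-04, and adjusted p = 0.80 with an estimated correlation). In limma 0 passed over all genes tested and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05, the cytochrome c oxidase subunit Cox5a at −0.31 (SE 0.12); the ATP synthase subunit Atp5me was at −0.25 (SE 0.11). Without vehicle replicate 3, or with scan day as a block, the median of this list was −0.07 and the call was lost (adjusted p = 0.091). With quantile normalisation it was −0.057 and the call was kept.

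**Figure D2:**
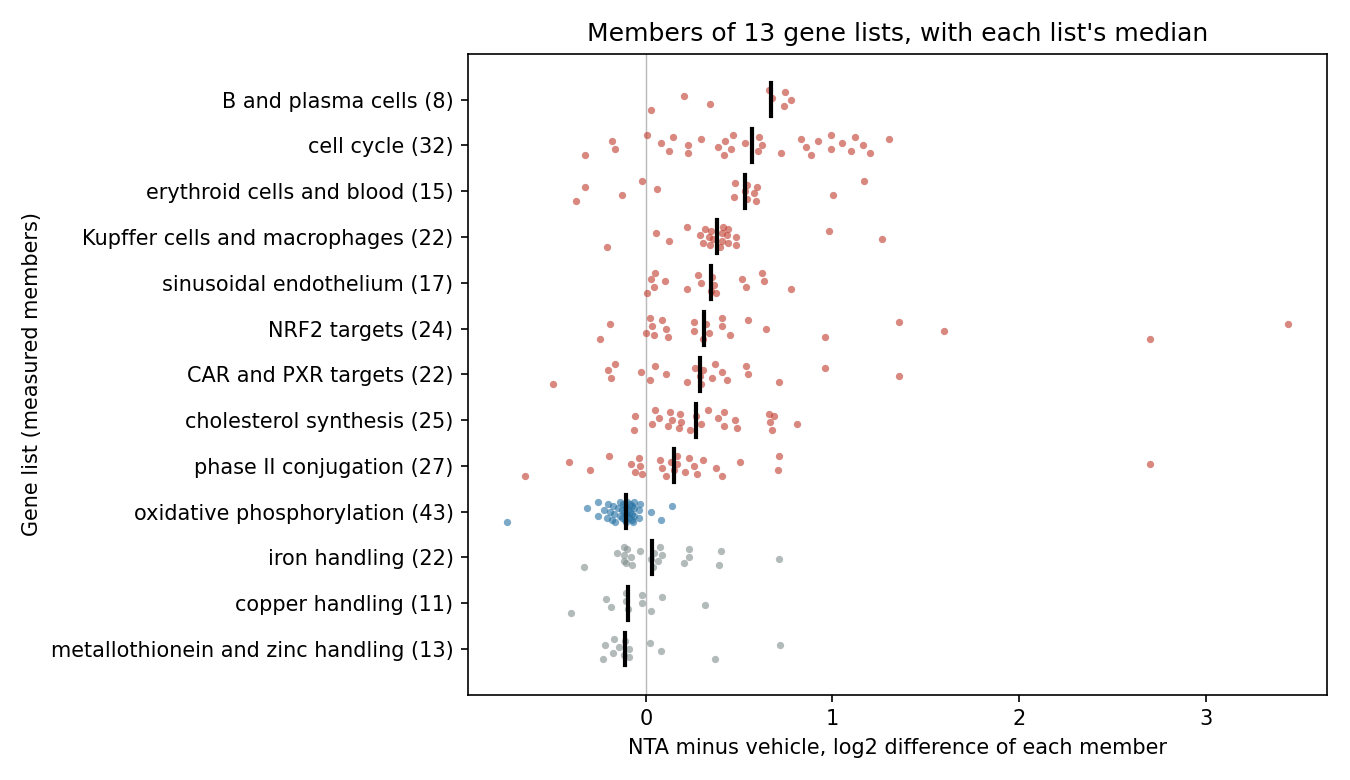
Log2 difference, NTA minus vehicle (horizontal axis, log2 units), of each measured member (points) of 13 gene lists, with the list's median (black bar) and the number of measured members in brackets; red lists shifted up and the blue list down by camera with the preset correlation, and grey lists did not shift. The medians run from 0.67 for B and plasma cell genes to −0.11 for the metallothionein and zinc list.

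The adipose tissue list was the 1 list past fry (adjusted p = 0.037), with Fabp4 the 1 member adjusted over the list alone and 0 over all genes tested in limma. Its median was −0.16 and its mean 0.27 over 7 genes (camera upward, adjusted p = 0.82, and adjusted p = 0.89 with an estimated correlation); after Fabp4, the smallest p belonged to Car3 at −0.36 (SE 0.18). The other 26 lists, among them PPAR-alpha, p53, heat shock, acute phase, interferon and circadian clock genes, did not pass camera, and their medians lay between −0.23 and 0.17.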

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

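The fits on named genes only and with scan day as a block, and the use of the median spot signal in normexp, were chosen after seeing the data. The count of 9 changed features was 7 to 13 in the alternatives chosen beforehand that kept all arrays, apart from the replicate block, and treat against a 1.2-fold change, run for the features changed at least 2-fold, gave 8. All 9 calls were kept under quantile, median and deposited values, array weights and slide as a random block. Normexp made 8 calls, 6 of them among the 9. Named genes only gave 4 changed, 4 higher and 4 at least 2-fold, because it tests fewer features. Leaving out 1 array gave 1 to 8 changed, 1 to 8 higher and 1 to 8 at least 2-fold, and trend and robust gave 1 lower. The replicate block gave 0 changed, 0 higher and 0 at least 2-fold in limma, with 2321 features at an unadjusted p under 0.05, and 10 lists. Deviations of same-numbered arrays correlated at 0.17, −0.01 and −0.07, so the numbers did not pair the samples, and not every sample correlated best with its own number. The 10 shifted lists became 16 with every probe on its own, 0 with an estimated correlation and 1 with fry, and 9 to 14 when 1 array was left out. The 16 include the AhR target list, which had under 5 measured members in the main fit and was not among its 41 lists. Of 1804 gene and list values under the alternatives, 1734 kept their direction and side of the threshold, 34 lost a call, 4 gained one and 32 changed sign. Most of these values had no call in the main fit to lose, so the 34 understate how often calls were lost. Among the called genes, Gstp1 passed in 18 of 21 settings, Tubb3 in 12 of 21, Cyp26a1 in 13 of 21 and Or4m1 in 12 of 20. Sign changes came in values that had no call: with normexp Cyp4a1 was at 0.13, Fasn at −0.033, G6pc1 at −0.093 and the iron list at −0.0496. Array weights put Fasn at −0.073 and every probe on its own put the biliary list at −0.0100. Scan day as a block gives the values found without vehicle replicate 3, the only array of day 2, with Hmox1 at −0.060, Cdkn1a at 0.0011, Fasn at −0.029 and Gclm at 0.014. When 1 array was left out, Tfrc ran from −0.19 to 0.13, Hmox1 from −0.060 to 0.23, Cdkn1a from −0.19 to 0.0011, Cyp2b1 from −0.046 to 0.16, Cyp4a1 from −0.27 to 0.085, Fasn from −0.27 to 0.47, Cyp7a1 from −1.61 to 0.025, G6pc1 from −0.33 to 0.44, Nqo1 from −0.59 to 0.48, Gclm from −0.55 to 0.055, the iron list from −0.029 to 0.084 and the biliary list from −0.061 to 0.26. Of 71 genes followed under the alternatives, 21 had a difference over 1.5 times smaller with normexp, sign changes included, and 3 one over 1.5 times larger, and 22 moved over 1.5 times when at least 1 of the arrays was left out. The offset of 50 in normexp is about as large as the median processed signal, 45.32 to 54.19 over the arrays. Adding it makes log2 differences of dim probes smaller by arithmetic, such as that of Fabp4 (−4.59 with vehicle), from 2.58 to 1.09. Lyve1, bright at 2.27 with vehicle, also fell, from 0.54 to 0.32, so the offset does not account for every gene. How many of the 21 it accounts for was not tested. The replicate block leaves fewer residual degrees of freedom than the 4 of the main fit, which makes very small p-values harder to reach. Other than this, the offset and the smaller number of features or arrays named above, the cause was not tested. Of the other 26 lists, 17 changed sign and 13 gained a call under at least 1 alternative. Signal over background limits Or4m1, whose vehicle signal was not above it.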

Other observations

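The tests of the other Gstp1 probes, of the slide and the scan day, and of macrophages and endothelium as a source of Fabp4, and the splits of the 4 gene counts, were chosen only after the result was seen.

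Several further genes that did not pass the threshold had large differences for their spread, and were named after their values were seen. Pdlim4, a cytoskeletal adaptor, was 4.28-fold higher with NTA (log2 2.10, SE 0.25; limma, Benjamini-Hochberg adjusted p = 0.17, and 0.012 to 0.58 over the alternatives). Pla2g7, a phospholipase that inactivates platelet-activating factor, was 4.08-fold higher (log2 2.03, SE 0.26; adjusted p = 0.26), and the heparan sulfate-cleaving enzyme Hpse 2.05-fold (log2 1.04, SE 0.14; adjusted p = 0.26). Sort1, a sorting receptor, was 1.65-fold higher (log2 0.72, SE 0.10; adjusted p = 0.26), and the endothelial receptor Cd93 2.12-fold (log2 1.08, SE 0.16; adjusted p = 0.36). The aldose reductase Akr1b1 was 1.94-fold higher (log2 0.96, SE 0.19; adjusted p = 0.45), beside Akr1b8 at 3.44 and Akr7a3 at 1.60 on the log2 scale. With normexp background correction Pdlim4 was at 1.29 and Sort1 at 0.41. In each of these 8 genes all 3 NTA rats lay above all 3 vehicle rats. Picking genes for a large difference relative to their spread favours this, so it adds no support.

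Some lists without a camera call held single genes with large differences. In lipid metabolism, the fatty acid transporter Cd36 was 2.87-fold higher (log2 1.52, SE 0.34; limma, Benjamini-Hochberg adjusted p = 0.48) and the glycerol channel Aqp7, above background on 2 of 3 vehicle arrays, had a log2 difference of 1.03 (SE 0.33), and of 0.18 with normexp background correction. In the list for unfolded protein and amino acid stress, the pseudokinase Trib3 was at 1.57 (SE 0.46) and cystathionine gamma-lyase (Cth) at −0.75 (SE 0.20). The clock genes Npas2 and Bmal1 were at −0.85 (SE 0.23) and −0.30 (SE 0.12), and the neutrophil genes S100a9 and S100a8 at 1.37 (SE 0.44) and 1.21 (SE 0.43). None of these passed, with adjusted p between 0.48 and 0.63.

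Each of the 9 changed features kept 0.940 to 1.05 times its log2 difference within the 5 arrays of day 1. These differences thus do not rest on the later scan of vehicle replicate 3. Calling features for a small spread within groups favours shares near 1, so the shares do not test scan day for other features. With 1 array fewer 5 of the 9 passed and 4 did not, among them Tubb3 at 1.89 (SE 0.16) against 2.01 (SE 0.17) and Cyp26a1 at 1.49 (SE 0.11) against 1.48 (SE 0.09). The slide stays open, since all NTA arrays share one and no vehicle array lies on it; with slide as a random block 9 features passed, which does not separate slide from treatment. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: the real split gave 9 changed, 9 higher and 9 at least 2-fold against a highest other count of 1, in 1 of 10 splits, and 0 lower against 1, which 10 of 10 splits reached. For gene lists, 5 of 10 splits gave as many as the real 10, and the highest other gave 15.

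Failure or cross-hybridisation of 1 probe as the source of the Gstp1 difference is argued against by its other probes, the lowest of which gave 2.68. Bile duct cells also carry Gstp1, but their marker list had a median of 0.065 (SD 0.45 over 15 genes), far below 2.70. Members already abundant in vehicle liver, such as Onecut1 at 4.01, would hardly move with a few more such cells, which this median cannot exclude. A candidate explanation is a wider response of NRF2 targets: without Gstp1 that list still had a median of 0.305 over 23 genes (camera, unadjusted p = 7.7e-09 against a smallest of 4.1e-06 in the other 9 splits, and unadjusted p = 0.021 with an estimated correlation, with which the whole list did not pass at adjusted p = 0.34). Of its other members, Akr1b8 and Akr7a3 lay well above 0 and Nqo1 at −0.19, Gclm at −0.25 and Hmox1 at 0.11 did not, and none of these 5 passed. Whether few cells with much Gstp1 or many with a little account for it was not tested, and the slide stays open.

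A large amount of adipose tissue in the NTA samples as the source of Fabp4 is argued against by the remaining 6 adipose markers, with a median of −0.19 (SD 0.25) against 2.58 for Fabp4. A small amount cannot be excluded this way. A marker such as Car3, at 4.26 in vehicle against −4.59 for Fabp4, would hardly move with it. Larger shares of macrophages or of endothelium, which also express Fabp4, are argued against in the same way by list medians of 0.379 (SD 0.29) and 0.351 (SD 0.24). A few cells of a kind rich in Fabp4, such as capillary endothelium, which markers already abundant in liver would hide, were not tested. Fabp4 was read by 1 probe, so failure or cross-hybridisation of that probe could not be checked against another. A change of Fabp4 in cells already present may remain, with the slide open as above.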
